A study of Mus musculus with 6 samples.

How the data were processed

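MIN6 is a mouse insulinoma line used as a model of the pancreatic beta cell. Per the labels, MIN6 cells received either a negative control siRNA or an siRNA against Hlxb9 (gene symbol Mnx1), a homeobox transcription factor, by nucleofection and a lipid reagent. Total RNA was taken 72 hours later. Several independent transfections were made, and RNA was put on arrays only from samples whose Hlxb9 protein was lower by more than 75% on a western blot, so the arrays were chosen by that result. The labels also describe the samples as sorted cells and name no gate. Each group has 3 arrays, numbered 1 to 3 in the titles, which are treated here as separate transfections.

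Biotinylated cRNA was made from 6 ug of total RNA and hybridised to an Affymetrix mouse expression array, per the labels. The deposited values are on a log2 scale. RMA, which corrects background, normalizes by quantiles and summarises the probes of each probe set, and Partek are named in the submitters' processing notes without versions. The RMA settings and the test the submitters used are not given in the sources used here. The table holds 45101 probe sets on 6 arrays. Median log2 values lie between 5.08 and 5.20 per array. Array signal gives no read depth, and the number of arrays limits the precision.

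The 64 control probe sets of the array maker were set aside, which left 45037 probe sets. In the platform annotation, 34945 of these have 1 gene symbol, 932 have several and 9160 are unnamed here. Entrez identifiers of 34741 probe sets matched a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes. Of the 9010 genes with several probe sets, 59.3% have probe sets whose differences go in opposite directions, so a value can depend on the probe set read. For each gene named by the rule below, other probe sets are given where any differed in the opposite direction by 0.1 log2 or more. This was so for 7 of the 24 genes named by p and 18 of the 87 named list members, of which 49 have other probe sets.

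Hlxb9 siRNA was compared with control siRNA by limma (version 3.58.1, R 4.3.3, statmod 1.5.0), with lmFit and eBayes on the log2 values, no covariate, two-sided tests and Benjamini-Hochberg adjustment over all 45037 probe sets, at an adjusted p of 0.05. Errors of differences are limma's moderated standard errors (SE). Group values are mean ± SD with n = 3. The level of Mnx1 also had an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. Gene lists, 22 in all with 439 of 488 entries matched to a gene on the array, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera was also run with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way by themselves, was a further alternative. The members of each list were also adjusted over the list alone. This made no adjustment over the 22 lists, so a passing member in some list can arise by chance.

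The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule names Mnx1, then 12 genes per direction among those past the threshold, and up to 4 members of each list with the smallest unadjusted p. The 12 genes per direction must have all 3 Hlxb9 siRNA values on one side of all controls and a mean in the higher group above the median of all probe sets. These conditions do not apply to Mnx1 or to list members, and 22 of the named list members lay below that median, 5.16, in both groups. Where fewer than 12 pass the threshold, as here, the remaining places go to the smallest unadjusted p in that direction under the same conditions. Genes known only by a clone or locus identifier are skipped, which passed over 2.

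The groups share replicate numbers. Deviations from the group means, over all probe sets, correlated between arrays of the same number with r of 0.155, 0.165 and 0.202, and between arrays of different numbers with r of 0.072 or lower. All 3 same-number values exceed 0.1, so the numbers were taken to pair the arrays. Deviations sum to 0 within a group, so the lower values between different numbers are partly forced and add little. This pairing comes from the values, since the labels state no shared day or culture. The fit with the replicate number as a block is an alternative, and its value stands beside a result where it changes the call.

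Other alternatives were centring each array on its median, repeating quantile normalization, an offset of 32 on the linear scale, leaving out dim probe sets, a mean-variance trend with a robust prior, array weights (limma arrayWeights, which gives less weight to arrays that fit the group means poorly), leaving out each array, other thresholds, the mean of a gene's probe sets, and plain _at probe sets alone. Array weights together with the block, array weights without each array, leaving out both arrays numbered 3, the count of unadjusted p values, and an estimated correlation under each setting that called a list, and the list members with the block, with array weights and without control replicate 3 were added after the data were seen. Bootstrap intervals are 95% intervals from 10000 resamples of genes.

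The limma comparison of Hlxb9 siRNA with control siRNA was tested on simulated data of 45037 probe sets with the real means and spreads, with 50 changed at each size. The changed probe sets were drawn only from those above the median signal, so recovery among dimmer ones was not tested. When the arrays varied as unequally as estimated here, the unweighted fit recovered 0% of changes of 0.5 log2, 66% of 1, 82% of 2 and 98% of 4. The weighted fit recovered 34%, 86%, 100% and 100% of the same sizes, with 4 false calls, and the fit with the replicate block 0%, 0%, 68% and 94%, with 0. In 100 simulations with no change, the most calls in any simulation was 0 with the unweighted or the weighted fit. The simulated noise was independent between probe sets and held no pair effect. These runs therefore do not show how often weights give false calls where probe sets vary together. Nor do they show how the block fit performs on paired arrays. In a simulated camera run on 18193 genes, a list shifted by 0.5 log2 had an adjusted p of 7.97e-47, and 0 other lists were called. Medians of the real lists ran only from -0.12 to 0.12 log2, so this run does not show whether shifts of that size are found. Nor does it show how often lists are called falsely where genes vary together. Camera with an estimated correlation was given no simulated shift. A call lost under it is therefore no evidence that the list did not differ.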

Results

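Gene expression was measured on 6 arrays of MIN6 mouse insulinoma cells, 3 after a control siRNA and 3 after an siRNA against Hlxb9 (Mnx1), a homeobox factor of beta cells and motor neurons. The comparison asks which transcripts differ when Hlxb9 protein is reduced. Values are log2 RMA signals. Correlations between arrays were 0.995 or higher, except that control replicate 3 correlated with the others at 0.988 to 0.991. The first principal component, with 59.2% of the variance, set control replicate 3 at 56.3 and the other 5 arrays between -16.3 and -4.77. On that array the Gapdh control probe set at the 3' end exceeded the 5' one by 2.13 log2, against 0.65 to 0.78 on the other arrays. For beta-actin the difference was 3.22, against 2.41 to 2.69. At most 0.442% of values were identical between any pair of arrays, so no array was a copy of another.

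Mnx1 transcript, read by its only probe set, was 7.70 ± 0.17 after control siRNA and 7.41 ± 0.13 after Hlxb9 siRNA (SD, n = 3 each). The difference of -0.29 ± 0.13 log2 (SE) corresponds to a level 18.0% lower and did not pass (limma adjusted p = 0.659, two-sided exact permutation p = 0.2 without pairing). Control arrays read 7.82, 7.50 and 7.77, and Hlxb9 siRNA arrays 7.53, 7.41 and 7.28, so Hlxb9 siRNA replicate 1 lay above control replicate 2. Within the pairs of equal number all 3 were lower after Hlxb9 siRNA, with differences of -0.28, -0.09 and -0.49 log2, and with the replicate block limma's adjusted p was 0.544. The 95% interval of the difference runs from -0.58 to 0.01 log2, whereas a transcript level lower by 75%, the size of the protein selection, would be -2 log2. The probe set was brighter than 69.8% of probe sets.

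**Figure D1:**
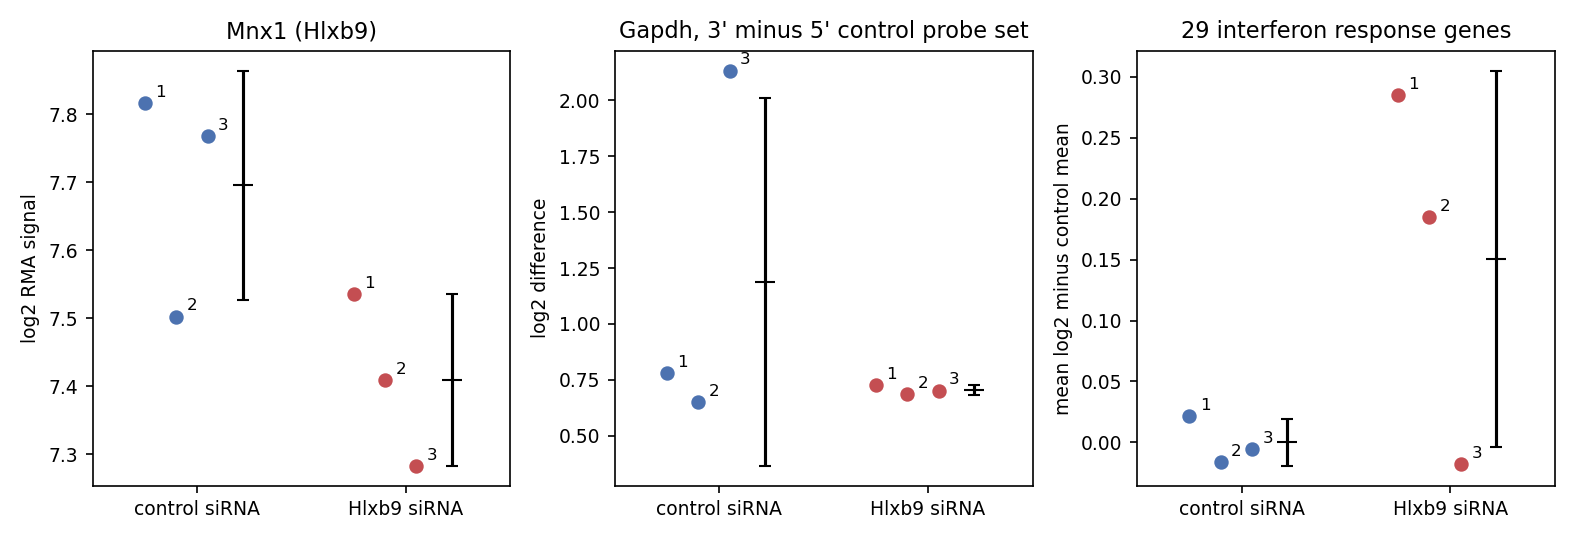
Mnx1 log2 signal (left), the log2 difference between the 3' and 5' Gapdh control probe sets (middle) and the mean log2 level of 29 interferon response genes relative to the control mean (right), with a point per array labelled by its replicate number and group means ± SD in black. Control replicate 3 stands at 2.13 for Gapdh, and Hlxb9 siRNA replicate 3 has the lowest Mnx1 signal, 7.28. The interferon list level of Hlxb9 siRNA replicate 3, -0.018, lies close to that of control replicate 2, -0.016.

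Among genes with higher signal after Hlxb9 siRNA, the smallest p belonged to Lcp2, the SLP-76 adaptor of antigen receptor signalling, at 6.82 ± 0.12 in controls and 7.75 ± 0.0033 after Hlxb9 siRNA, 1.91-fold. Nrk, a kinase of the germinal centre kinase family, was 2.18-fold higher (1.12 ± 0.13 log2, SE), and Ifih1, the cytosolic sensor of double-stranded RNA known as MDA5, was 2.03-fold higher (1.02 ± 0.13). Apof, a lipoprotein component, differed by 0.97 ± 0.15, Pcyt1b, a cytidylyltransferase of phosphatidylcholine synthesis, by 0.88 ± 0.15, and Fbp2, the muscle fructose bisphosphatase, by 0.70 ± 0.12. Serpina1c, from the alpha-1-antitrypsin family whose mouse copies are closely alike, differed by 0.75 ± 0.11. Pid1 differed by 0.81, Atp4a, the catalytic subunit of the gastric proton pump, by 0.61, Synpo2 by 0.60, the klotho gene Kl by 0.58 and the endocytic collagen receptor Mrc2 by 0.51. Second probe sets differed in the same direction for Lcp2 (1.05), Nrk (0.69 and 0.80), Kl (0.49) and Pcyt1b (0.46). The other probe sets of Pid1 lay between -0.23 and 0.06, and that of Mrc2 at -0.19.

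Among genes with lower signal, Synpo2l stood at 6.22 ± 0.12 in controls and 5.28 ± 0.25 after Hlxb9 siRNA, 1.92-fold lower. Kcnk3, a background potassium channel, differed by -0.78 ± 0.17 log2 (SE), Ube2w, a ubiquitin-conjugating enzyme, by -0.70 ± 0.14, and Rab3a, a GTPase of secretory vesicle exocytosis, by -0.70 ± 0.13. The collagen receptor kinase Ddr1 differed by -0.63 and Nf1, the Ras GTPase-activating protein neurofibromin, by -0.60. Tmem64 differed by -0.64, the protein phosphatase subunit Ppp1cb by -0.56, the kinase Wnk2 by -0.53, the Notch-like ligand Dner by -0.52, Aktip by -0.50 and Eef2k, the kinase that restrains translation elongation, by -0.48. Probe sets of 4 of these 12 genes (Ddr1, Rab3a, Ppp1cb and Dner) carry the _x_at suffix, which marks probes that can bind related sequences. The other probe set of Rab3a differed by 0.04, those of Tmem64 by 0.02 and 0.28 and that of Dner by -0.09, while all 3 others of Ppp1cb were lower, from -0.64 to -0.34. Those of Synpo2l lay between -0.18 and 0.32, of Ddr1 between -0.83 and 0.22, of Ube2w between -0.15 and 0.17 and of Aktip between -0.26 and 0.19. The plain _at probe sets of Ddr1 differed by -0.09, 0.15 and 0.22. For 5 of the 12 genes every other probe set was also lower, but only those of Ppp1cb had an unadjusted limma p under 0.05. The others stood at -0.03 and -0.04 for Nf1, -0.09 for Dner, -0.17 and -0.10 for Eef2k and -0.29 and -0.07 for Kcnk3. With the mean of a gene's probe sets, 13 of the 24 named values were smaller by over 1.5 times, at -0.11 for Tmem64, -0.17 for Ube2w, -0.18 for Wnk2, -0.19 for Synpo2l and Aktip, -0.22 for Nf1, -0.25 for Eef2k, -0.28 for Ddr1, -0.30 for Dner, -0.33 for Rab3a, -0.38 for Kcnk3, 0.16 for Mrc2 and 0.21 for Pid1. With the offset this was so for 4, with Ifih1 at 0.62, Pcyt1b at 0.55, Synpo2l at -0.59 and Kcnk3 at -0.44. Across the array the 2441 _x_at probe sets had a median difference of -0.07, against 0.01 for all others, and -0.03 without control replicate 3.

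**Figure D2:**
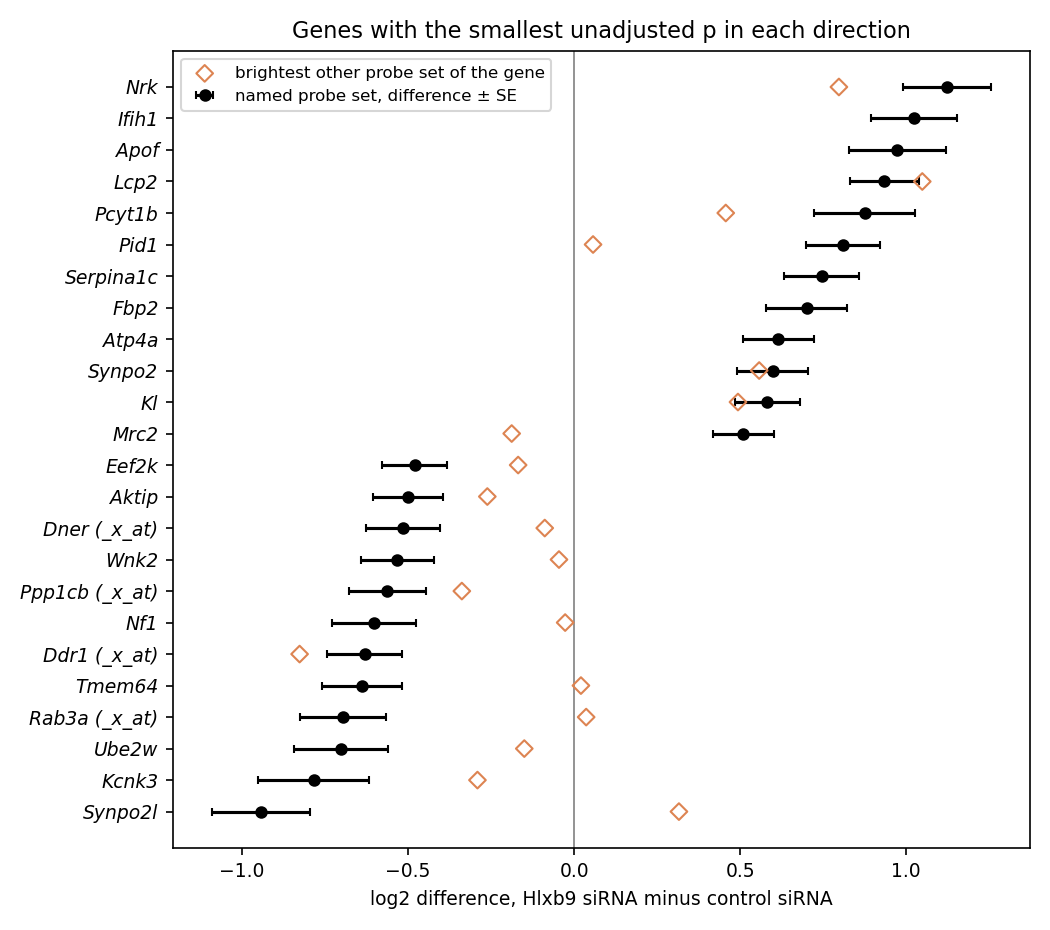
Log2 difference (Hlxb9 siRNA minus control siRNA) of the 12 named genes in each direction, with black points for the named probe set ± SE and open diamonds for the brightest other probe set of the gene. Second probe sets of Lcp2, Nrk and Kl lie on the same side as the first, and those of Pid1, Rab3a and Tmem64 lie near 0.

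None of these 24 genes passed the threshold (limma adjusted p from 0.623 to 0.645), and they are given as values. Limma called 0 probe sets higher and 0 lower, with a smallest adjusted p of 0.623. At an unadjusted p of 0.05 there were 3430 probe sets, 7.62% of those tested, 1738 higher and 1692 lower, where chance alone gives about 2252. Leaving out either of 2 Hlxb9 siRNA arrays ended this excess, with 933 higher and 824 lower without replicate 1 and 921 and 908 without replicate 2. After centring each array on its median this split was 963 higher and 2346 lower. In genes, 766 were higher and 680 lower at that p. All 3 Hlxb9 siRNA values lay on one side of the controls for 7008 probe sets, 15.6%, where chance gives 10%. Differences ranged from -1.24 to 1.46 log2, with 11 probe sets at least 2-fold higher and 6 at least 2-fold lower.

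Array weights were 0.628, 4.46 and 0.204 for control replicates 1, 2 and 3, and 0.758, 2.91 and 0.792 for Hlxb9 siRNA replicates 1, 2 and 3. The weighted values therefore rest mostly on the arrays numbered 2. With these weights limma called 579 probe sets higher and 553 lower, or 270 and 185 genes. All 24 genes above were among them (adjusted p from 0.00979 to 0.0401). The weighted fit called 0 probe sets when any of the 6 arrays was left out. The unweighted fit without control replicate 3 called 0, and the replicate block also called 0 (smallest adjusted p = 0.478, 4191 probe sets at an unadjusted p of 0.05).

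Ins2, encoding insulin, read 13.85 ± 0.02 in controls and 13.81 ± 0.02 after Hlxb9 siRNA, (SD, n = 3), and Pdx1, a master regulator of the beta cell, differed by -0.11 ± 0.10 log2 (SE). Of 26 measured beta cell identity genes, 9 were higher and 17 lower, with a median of -0.03, a mean of 0.00068 and camera's direction downward (adjusted p = 0.621). The incretin receptor gene Gipr differed by 0.28 ± 0.12 (SE), the islet glucose phosphatase G6pc2 by -0.23 ± 0.10, the endocrine transcription factor Insm1 by -0.40 ± 0.18 and the prohormone-processing enzyme Cpe by -0.27 ± 0.13. In the list of other islet hormones and their regulators, 4 of 12 members were higher and 8 lower, with a median of -0.05, camera's direction downward and a mean of 0.05 (adjusted p = 0.621). Ppy, encoding pancreatic polypeptide, had a wide spread, 8.95 ± 1.42 and 10.09 ± 1.33 (SD), Ghrl differed by -0.45, Irx1 by -0.25 and Rbp4 by 0.27. Of 19 genes kept low in mature beta cells, 11 were higher, with a median of 0.05 (-0.0022 after centring) against a downward direction in camera (adjusted p = 0.99). Lmo4 differed by 0.44, Cd302 by 0.42, Acot7 by -0.37 and Yap1 by -0.42. Motor neuron and interneuron genes, where Mnx1 also acts, had 8 of 14 members higher and a median of 0.04, again against camera's downward direction (adjusted p = 0.99). Sox14 differed by -0.38, the vesicular acetylcholine transporter Slc18a3 by 0.30, Sim1 by -0.20 and Lhx4 by 0.21 (other probe set -0.18). Without control replicate 3, Insm1 stood at -0.22, Cpe at -0.15, Ghrl at -0.19, Irx1 at -0.16, Ppy at 0.32 and Cd302 at 0.10. Leaving out that array breaks its pair, and Ppy was low on both arrays numbered 3. Within the pairs Ppy differed by 1.08, 1.08 and 1.23 log2. With the replicate block it passed over its list alone (limma adjusted p = 3.88e-04), not over all probe sets (0.478).

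Genes of S phase and mitosis were split, 14 higher and 17 lower of 31, with a median of -0.02 (camera adjusted p = 0.621) and of 0.02 without control replicate 3. Ccne2, a cyclin of S phase entry, differed by -0.41 ± 0.11 (SE) and Ube2c by 0.30. The replication licensing gene Mcm4 differed by -0.48 ± 0.13 and Rrm2 by -0.24, both on _x_at probe sets, while the other probe set of Mcm4 differed by -0.10 and those of Rrm2 by -0.31 to 0.0071. Among 16 G1 cyclins, kinases and inhibitors the median was 0.03 (-0.01 after repeated quantile normalization, adjusted p = 0.99). The CDK inhibitor Cdkn1b (p27) differed by -0.37 ± 0.11, with its other probe set at 0.18, Cdkn2a by 0.49 ± 0.18, Ccnd2 by 0.26 and Rb1 by -0.20. Apoptosis genes were 11 higher and 11 lower of 22, with a median of 0.02 (camera adjusted p = 0.592). The median was -0.03 after centring and 0.07 without control replicate 2. The list mean of all 3 Hlxb9 siRNA arrays lay above all controls, which chance gives, in either direction, in 10% of lists. Relative to the control mean, Hlxb9 siRNA replicate 2 stood at 0.0452 and control replicate 2 at 0.0441, so the groups barely separated. Casp9 differed by 0.39, though its other probe sets differed by -0.43 and -0.08, the BIM gene Bcl2l11 by 0.35, Bcl2 by 0.21 and Xiap by -0.22 (others -0.28 to 0.18). Targets of p53 had a median of -0.01, a mean of 0.03 and an upward direction in camera (20 genes, adjusted p = 0.905), with Btg2 at 0.38, Sesn2 at -0.36 but at 0.41 on its other probe set, Phlda3 at -0.28 and Eda2r at 0.24. Immediate-early genes had a median of 0.0011, a mean of -0.03 and a downward direction (21 genes, adjusted p = 0.905, median -0.05 without control replicate 3). Btg2, which is also in this list and had its smallest p, was higher by 0.38. Egr3 differed by -0.43, and Myc by -0.62 ± 0.36 on a dim probe set, 4.34 in controls. Fosl1 differed by -0.47 on a dim probe set, 3.59 in controls, and by 0.35 on the other. Myc stood at -0.15 without control replicate 3, Ube2c at 0.07 and Ccnd2 at 0.11.

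The interferon response list had the smallest p of the 22. Of its 29 members, 21 were higher and 8 lower, with a median of 0.11, and camera's adjusted p was 0.0545, just outside the threshold, and adjusted p = 0.867 with an estimated correlation. The median was 0.064 without Hlxb9 siRNA replicate 1 (adjusted p = 0.458), 0.069 without control replicate 2 (adjusted p = 0.134) and 0.056 with the offset (adjusted p = 0.0522). After centring it was 0.053 and passed (adjusted p = 0.0229, and adjusted p = 0.781 with an estimated correlation). Beside Ifih1, the deubiquitinase of ISG15 Usp18 differed by 0.34 ± 0.12 (SE), Ifit3 by 0.48 ± 0.20 and the chemokine Cxcl10 by 0.30 ± 0.13. Ifih1 passed when adjusted over the list alone (adjusted p = 0.00165) and not over all probe sets (0.623). With the replicate block the list passed (adjusted p = 0.0326, and adjusted p = 0.922 with an estimated correlation), and with array weights it also passed (adjusted p = 0.0372, and adjusted p = 0.851 with an estimated correlation). Relative to the control mean, the list mean was 0.29 in Hlxb9 siRNA replicate 1, 0.19 in replicate 2 and -0.018 in replicate 3. The last lay barely below the lowest control, control replicate 2 at -0.016.

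Unfolded protein response genes leaned the other way, with 19 of 23 lower and a median of -0.07 (camera adjusted p = 0.117, median -0.12 after centring). The list mean of all 3 Hlxb9 siRNA arrays lay below all controls, a separation that chance gives, in either direction, in 10% of lists. Xbp1, a transcription factor of this response, differed by -0.29 ± 0.10 (SE), the co-chaperone genes Dnajc3 by -0.31 ± 0.11 and Dnajb9 by -0.17, and Atf3 by -0.31 ± 0.13. Without control replicate 3 the list passed with a median of -0.05 (adjusted p = 0.0301, and adjusted p = 0.739 with an estimated correlation).

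In metabolism, cholesterol synthesis genes were higher in 12 of 18, with a median of 0.05 (camera adjusted p = 0.224). The list mean of all 3 Hlxb9 siRNA arrays lay above all controls, a separation that chance gives, in either direction, in 10% of lists. The median was 0.0014 after centring and 0.0074 with the mean of each gene's probe sets, and 0.012 without Hlxb9 siRNA replicate 1 and 0.10 without replicate 3. The sterol carrier Stard4 differed by 0.36 ± 0.10 (SE), Hsd17b7 by 0.41 ± 0.13 on an _x_at probe set (others -0.23 to 0.24), Pmvk by 0.22 and Nsdhl by 0.20. Glycolysis and hypoxia genes were higher in 17 of 21, with a median of 0.12 (adjusted p = 0.364), of 0.06 without control replicate 3 and of 0.05 without Hlxb9 siRNA replicate 2. Without Hlxb9 siRNA replicate 3 the list passed (camera adjusted p = 0.0388, and adjusted p = 0.802 with an estimated correlation). The 4 members with the smallest p were Adm at -0.56 on an _x_at probe set, the oxygen-regulated hydroxylase Egln3 at 0.37, Hk1 at -0.37 with its other probe set at 0.22, and Vegfa at -0.19. With the replicate block Adm passed over its list alone (limma adjusted p = 0.037), not over all probe sets (0.482). Respiratory chain and ATP synthase genes were higher in 21 of 30, with a median of 0.06 (0.0094 after centring, adjusted p = 0.287). Ndufb3 differed by 0.33 and Sdhc by 0.17, Cox6c by 0.25 with its other probe set at -0.16, and Uqcrb by -0.23 with its other at 0.10. Fatty acid and lipid genes had a median of -0.04 in 24 genes (adjusted p = 0.887) and of 0.0016 without control replicate 3. Hadhb differed by -0.51 on an _x_at probe set and by 0.20 and 0.22 on its others, and Hadha, the partner subunit of the same enzyme, by 0.31. Dgat1 differed by 0.38 and Plin2 by 0.25. Ribosomal protein genes had a median of 0.0047 in 20 genes (-0.05 after centring, adjusted p = 0.905), with Rps3 at 0.17, Rpl8 at 0.16, and on _x_at probe sets Rps24 at -0.14 (others -0.21 to 0.12) and Rpl37 at -0.22. Growth factor signalling genes were 13 higher and 12 lower, with a median of 0.02 (adjusted p = 0.99) and of -0.08 without control replicate 3. Cbl, a ubiquitin ligase of receptor kinases, differed by 0.53 ± 0.16, with other probe sets at -0.25 and -0.19, Gsk3b by -0.33 (others -0.26 to 0.14), Spry4 by -0.42 (others -0.12 to 0.12) and Egfr by 0.35 (others -0.35 to 0.11). With control replicate 3 left out, Hk1 stood at -0.15, Ndufb3 at 0.19, Hadhb at -0.30, Spry4 at -0.21 and Egfr at 0.14.

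Markers of other cell types were tested in 5 lists, and none passed. Their medians over all members lay below 0, but few members were above the median signal, and over such members alone 4 medians lay above 0, macrophage at 0.27 over 3 members, which is the value of C1qa, fibroblast at 0.11 over 4, acinar at 0.10 over 3 and duct at 0.04 over 5, and endothelial at -0.03 over 2. Fibroblast genes had a median of -0.10 in 17 genes (camera adjusted p = 0.224), with Col5a1 at -0.43, Vim at -0.50 on an _x_at probe set, Sparc at -0.27 and Col6a1 at -0.21. Macrophage and leukocyte genes had a median of -0.12 in 14 genes (adjusted p = 0.588). In that list the lysosomal glycoprotein Cd68 differed by 0.54 ± 0.13 (SE) and passed when adjusted over the list alone (limma adjusted p = 0.0473), not over all probe sets (0.645). Without control replicate 3 Cd68 did not pass over the list alone either (limma adjusted p = 0.0776). Csf1r differed by -0.36, C1qb by -0.25 and C1qa by 0.27. Endothelial genes had a median of -0.08 in 12 genes (adjusted p = 0.27), with Pecam1 at -0.28, Kdr at -0.26, Eng at -0.25 and Vwf at -0.16. Acinar genes had a median of -0.07 in 14 genes (adjusted p = 0.621), with Cela3b at -0.24, Cela2a at -0.24, Prss2 at -0.17 on an _x_at probe set and Rbpjl at 0.24 (other -0.19). Duct genes had a median of -0.06 in 11 genes (adjusted p = 0.621), with Tspan8 at -0.35 (others -0.15 to 0.23), Cldn4 at -0.14, Muc1 at -0.13 and Cftr at 0.16. Leaving out control replicate 3 gave C1qa 0.055, Prss2 -0.012, Kdr -0.08, Sparc -0.18, Muc1 -0.05 and Cftr 0.07.

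Camera called 0 of the 22 lists, with 4 at an unadjusted p of 0.05. It called 0 with an estimated correlation (smallest adjusted p = 0.867), and fry called 0 (smallest adjusted p = 0.383). Neither alternative was tried on a simulated shift, so these results cannot show that no list differed. Camera called 1 each with the replicate block, with array weights and without control replicate 3, and these calls were lost with adjusted p = 0.922, 0.851 and 0.739 with an estimated correlation. In every list 0 members passed over all probe sets in the main fit, and adjusted over the list alone 0 passed apart from Ifih1 and Cd68. Without control replicate 3, Cd68 did not pass over its list alone (limma adjusted p = 0.0776), while Ifih1 (0.00246) and Ifit3 (0.03) did. With array weights further named members passed over their list alone, among them Ccne2 and Mcm4 (0.0386), Casp9 (0.0167) and Csf1r (0.00373). With the replicate block 0 passed over all probe sets and 5 over the list alone, Ppy (adjusted p = 3.88e-04), Ifih1 (0.00514), Ucn3 at 0.59 ± 0.11 (0.0335), Adm (0.037) and Cd68 (0.0492), of which Ucn3 is named after its value was seen. With array weights 9 of the 439 members passed over all probe sets, Ifih1, Ifit3, Casp9, Stard4, Cbl and Lmo4 higher and Egr3, Fosl1 and Csf1r lower (adjusted p from 0.0245 to 0.0479). Without control replicate 3, 20 of the 88 named list entries were smaller by over 1.5 times and 0 turned. Each list median moved by over 1.5 times in at least 3 of its 19 alternatives, and 16 of the 22 changed sign in some.

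**Figure D3:**
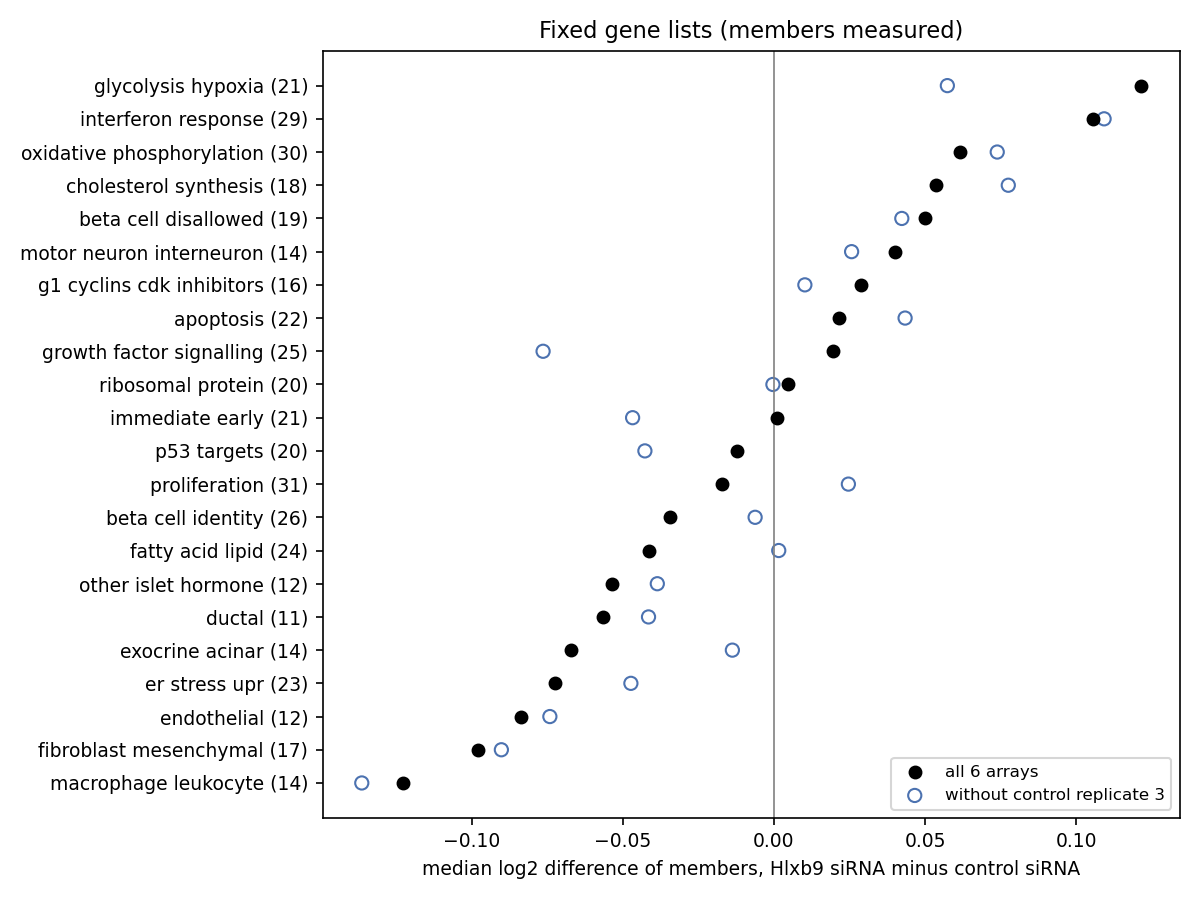
Median log2 difference (Hlxb9 siRNA minus control siRNA) of the members of each of the 22 lists, with the number of members measured in brackets, for all 6 arrays (black) and without control replicate 3 (open circles). Medians of all 6 arrays run from -0.12 to 0.12, and growth factor signalling moves from 0.02 to -0.08 when control replicate 3 is left out.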

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

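The tests of control replicate 3, of both explanations of the _x_at shift and of the splits of probe set counts were chosen after those results were seen.

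Outside the tested probe sets, 2 of the 64 control probe sets of the array maker were flagged as differing between groups. This is no more than the about 5% that chance flags. The flagged 2 read the 5' ends of Bacillus transcripts added as controls, and on both every Hlxb9 siRNA array lay above every control array. The lys 5' probe set differed by 0.65 log2 (5.50 ± 0.47 in controls, 6.15 ± 0.22 after Hlxb9 siRNA, SD, n = 3) and the thr 5' probe set by 0.79 (3.50 ± 0.59 and 4.29 ± 0.18). Both were lowest in control replicate 3, at 4.99 and 2.87. The mean over 8 Bacillus 5' probe sets was 5.54 in control replicate 1 and 5.51 in Hlxb9 siRNA replicate 1, so there the groups overlapped.

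Control replicate 3 had low signal at 5' ends of mouse and bacterial transcripts alike. The Bacillus controls, which do not come from the cells, differed between 3' and 5' ends by 6.17 log2 on that array. On the other 5 arrays they differed by 4.94 to 5.23. This argues against decay of the RNA before these controls were added as the whole cause. It cannot exclude some decay of the cell RNA as well. A shorter product of the labelling reaction may account for the pattern. Both mouse control genes exceeded every other array by at least 0.53 log2, but that excess prompted the question and is no independent evidence. No biological explanation was tested.

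Probe sets with the _x_at suffix lay lower after Hlxb9 siRNA, and 84 of the 93 with an unadjusted p under 0.01 were lower (90.3%), against 230 of 551 others (41.7%). Control replicate 3 as the whole cause is argued against, because without it the groups still differed by -0.049 log2 in the _x_at median relative to other probe sets (-0.080 with it), with a pooled SD of 0.0041 between arrays. Lower transcript levels of the annotated genes as the whole cause are argued against as well. Over all 1470 genes with both kinds, the _x_at probe set differed between groups by a median of -0.07 and the brightest other probe set by 0.02, and the difference within a gene had a median of -0.094 (95% bootstrap interval -0.11 to -0.08, and -0.06 without control replicate 3). Binding of a related sequence or a difference in labelled material between groups may remain, and neither was tested.

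Interferon response genes leaned higher after Hlxb9 siRNA. Without Ifih1 the other 28 members, 20 higher and 8 lower, had a median of 0.10 log2 (95% bootstrap interval 0.02 to 0.18, against 0.0023 for all genes). Leaving out a single member can hardly move a median, and the interval resamples genes, not arrays. This test therefore cannot decide how far the lean of the list rests on Ifih1. The list without Ifih1 did not pass in camera (adjusted p = 0.134), and its call with the replicate block was lost (adjusted p = 0.0924, and adjusted p = 0.93 with an estimated correlation). A response to the siRNA rather than to lower Hlxb9 cannot be told apart from an effect of Hlxb9, because each siRNA, from its own supplier, was used in 1 group only, on 3 arrays. An effect of Hlxb9 on these genes stays open and untested.

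With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split gave 1132 probe sets with array weights and the highest of the other splits 0, so 1 of 10 reached that number. Without weights all 10 splits gave 0 probe sets, the real one included. At an unadjusted p of 0.05 the real split gave 3430 and the highest other 3819, so 2 of 10 reached it, and among the 4 splits that part every pair of equal number the highest other gave 2173. For gene lists the real split gave 0 calls, a number that all 10 reach by construction, and the highest other gave 5, so neither comparison with 0 tests anything.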

How the results depend on the processing

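Array weights with the replicate block, array weights without each array, leaving out both arrays numbered 3, the unadjusted counts, the estimated correlation under each setting and the members under the block, array weights or without control replicate 3 were chosen after seeing the data. Calls of probe sets stayed at 0 in either direction except with array weights (579 higher and 553 lower, 270 and 185 genes), with array weights and the replicate block (1193 and 1130, 506 and 432 genes, 1083 probe sets shared with array weights alone), and at an unadjusted p of 0.05 with 1.5-fold (175 and 133, 67 and 26 genes). Mnx1 kept its direction and stayed outside the threshold in all settings run, from -0.38 to -0.14 log2 (adjusted p 0.308 to 0.958, and 0.544 with the replicate block at -0.29). Having 1 probe set, it has no mean of several to try, and that setting was not run. At an unadjusted p of 0.05, leaving out an array gave 933 higher and 824 lower without Hlxb9 siRNA replicate 1, 921 and 908 without replicate 2 and 1595 and 1571 without replicate 3, and 2211 and 2378, 1659 and 1328, and 2493 and 1791 without control replicates 1, 2 and 3. The replicate block raised the lists called from 0 to 1, interferon response, at 0.11, added Ppy, Ucn3 and Adm to the members past the threshold over their list alone, and changed no other call. The number of lists called was also 1 after centring, with the offset, above the median signal, with array weights, with plain _at probe sets, with array weights and block, and with the block without both arrays numbered 3, and was 2 with the mean of a gene's probe sets and 0 to 2 when an array was left out. The interferon list passed after centring (median 0.053), with array weights (0.12), with the mean of probe sets (0.11), with plain _at probe sets (0.13), with array weights and block (0.16) and with the block without both arrays numbered 3 (0.16). Under the 9 settings that called it, those with an array left out included, its adjusted p ran from 2.80e-04 to 0.0495, and the call was lost with adjusted p = 0.485 to 0.922 with an estimated correlation. The unfolded protein response list passed with the offset (-0.072), above the median signal (-0.072) and with the mean of probe sets (-0.11). All 5 of its calls, those with an array left out included, had an adjusted p from 0.0172 to 0.044 and were lost with adjusted p = 0.739 to 0.947 with an estimated correlation. With an array left out, medians ranged from 0.064 to 0.15 for interferon, which passed without control replicate 1 or Hlxb9 siRNA replicate 3, from -0.11 to -0.047 for the unfolded protein response, which passed without control replicate 3 or Hlxb9 siRNA replicate 2, and from 0.046 to 0.20 for glycolysis and hypoxia, which passed without Hlxb9 siRNA replicate 3 (adjusted p 0.0388, and adjusted p = 0.802 with an estimated correlation). The 24 named genes kept their direction in all 336 alternative values and passed in 24, all with array weights. Of these genes, 13 were smaller by over 1.5 times with the mean of probe sets and 4 with the offset. The naming rule required every Hlxb9 siRNA value on one side of all controls. Leaving out an array, array weights, the block, the trend, leaving out dim probe sets and the offset therefore could not turn a direction. Only centring, quantile normalization and the mean of probe sets could. Over 418 alternative values of the lists, 15 passed, 0 reversed a call and camera's direction turned in 60 without a call, in 12 lists, and the median's sign in 63, in 16 lists. The cause was not tested for any of these. Array signal near background limits what dim probe sets can show.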

Other observations

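The genes named here were chosen after their values were seen, and the fit with array weights called 0 probe sets when any of the 6 arrays was left out. The weighted values rest mostly on the arrays numbered 2, with weights of 4.46 for control and 2.91 for Hlxb9 siRNA.

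The fit with array weights called 150 genes higher and 57 lower whose Hlxb9 siRNA values all lay on one side of the controls above the median signal. Among those not yet described, the endocrine transcription factor Pax4, which directs islet progenitors toward beta and delta cells, was 1.67-fold higher (0.74 ± 0.11 log2, SE, adjusted p = 0.0344 with array weights, 0.66 ± 0.20 without). Also called higher with array weights were the interleukin receptor genes Il6ra at 0.67 and Il15ra at 0.61, Vegfd, a lymphatic growth factor, at 0.68, and Sema5a at 0.77, though another probe set of Sema5a stood at -0.24. Cyp4v3, a fatty acid hydroxylase, stood at 1.01 and Pipox, a peroxisomal oxidase, at 0.94. Called lower with array weights were Efnb2, an ephrin ligand, at -0.64, the homeobox gene Hoxa7 at -0.67, the membrane protease St14 at -0.57 and Nol3, an inhibitor of cell death, at -0.57. With array weights, other probe sets stood at 0.11 for Il6ra, 0.22 for Il15ra, 0.17 to 0.61 for Vegfd and 0.68 for Cyp4v3. They stood at -0.24 to 0.23 for Sema5a, -0.39 to -0.03 for Efnb2 and -0.15 for Nol3.

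Ppy differed little in size between pairs of equal number while its level varied widely between them. It read 9.86, 9.68 and 7.32 in control replicates 1, 2 and 3 and 10.95, 10.76 and 8.55 in Hlxb9 siRNA replicates 1, 2 and 3, so each pair differed by 1.08 to 1.23 log2. With the replicate block the difference of 1.13 had an SE of 0.11, against 0.81 without it, and limma's adjusted p was 0.478 over all probe sets, so it did not pass there. The glucose transporter gene Slc2a2 went the other way between numbers, at 9.21, 9.27 and 10.17 in controls and 9.38, 9.46 and 10.29 after Hlxb9 siRNA. Glycolysis and hypoxia genes also followed the replicate number. Averaged over both arrays of a number, the list mean lay at -0.0098 for number 1, 0.19 for number 2 and -0.18 for number 3, while Hlxb9 siRNA differed from control by 0.17, 0.12 and -0.03 within these pairs. Ldha, a lactate dehydrogenase gene, read 10.72, 11.28 and 10.01 in controls and 11.19, 11.48 and 9.90 after Hlxb9 siRNA.

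Men1, the gene of the menin tumour suppressor, differed by -0.17 ± 0.16 log2 (SE, limma adjusted p = 0.803), by 0.011 without control replicate 3 and by -0.35 to 0.12 on its other probe sets, and Cblb, a ubiquitin ligase gene, by 0.09 ± 0.15 (0.884) and by -0.02 without control replicate 3, and neither passed.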
